A study of Rattus norvegicus with 12 samples.

How the data were processed

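Gene expression was measured in the basolateral amygdala (BLA), a forebrain region of mostly glutamatergic neurons that links sensory cues to emotional value, of male Long-Evans rats. Per the labels, rats had an extra bottle with up to 4 mL of 30% sucrose or of water 2 times a day for 14 days, with free chow and water, and the BLA was taken on the morning of day 15. The BLA of both sides from 2 rats of one group was pooled for each RNA sample, so that 24 rats gave 12 samples, 6 from the sucrose group and 6 from the water control. Each array is therefore an independent pool, and the unit of replication is the pool and not the rat.

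Biotin-labelled RNA was hybridised to Affymetrix whole-genome rat arrays of short oligonucleotide probe sets. The submitters' processing notes name RMA, a method that corrects background, equalises the distributions of arrays and summarises the probes of a set, with no version. The deposited values are linear ratios: for each probe set the mean of the 6 control arrays was 1, within 2e-07, so each deposited ratio is the signal on an array over the mean signal of the controls. The absolute signal is not kept in such a ratio. No dim probe set could be recognised, no gene could be ranked by its level, and levels of different genes cannot be compared. Whether arrays were scaled again after RMA is not given in the sources used here. The median ratio per array ran from 0.989 in sucrose array 1 to 1.002 in control array 3. The precision of every value is limited by the number of arrays.

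A second deposited table holds 145 probe sets with a p-value, a mean ratio of the controls and a mean ratio of the sucrose arrays, per the file headers. The test behind these deposited p-values is not named there. All 145 were equal, within 1%, to those of a two-sided Welch test on log2 ratios, without adjustment.

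The value table had 31099 probe sets. The 57 control probe sets of the manufacturer were left out of tests and used as measures of hybridisation (bacterial and phage spike-ins) and of RNA integrity (3-prime minus 5-prime signal of Gapdh and beta-actin), leaving 31042. The platform annotation gave 1 gene symbol to 20826 of these, several to 436 and none to 9780. Of the symbols, 20758 were matched by gene identifier to the RefSeq gene table of assembly GRCr8 and 0 changed. Genes were named only from probe sets with 1 symbol, which covered 14217 genes.

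Log2 ratios were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided), with Benjamini-Hochberg adjustment over 31042 probe sets and a threshold of 0.05. The design fixed before the data were examined had a variance trend with signal level. Because ratios to the control mean keep no level, the prior variance was fitted here without the trend, and the fit with the trend is given as an alternative. Both gave 0 calls. The procedure was tested on simulated data with the residual spread of these arrays. Of 50 probe sets changed by 0.25 on the log2 scale 31 were recovered, and of 50 changed by 0.5 45. Of 50 changed by 1 and 50 changed by 2 all were, with 11 false calls over the 31042 tested. All these changes were put into the same simulated data set, with independent normal noise. Many large changes loosen the adjusted threshold, so these shares do not give the power to find few or small changes in the real data.

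A total of 29 gene lists (transmitter systems, plasticity and signalling, metabolism, hormones, the clock, and markers of the cell types a BLA dissection could hold) were fixed before the data were examined. Each gene was represented by its probe set of highest variance over the 12 arrays. Lists were tested with camera in limma at its preset correlation of 0.01, which asks whether a list shifts relative to all other genes, with adjustment over the 29 lists. Beside it stand camera with an estimated correlation, fry, which asks whether the members of a list move one way and compares them with no other genes, and an exact permutation test of the list mean over all 924 assignments of the 12 arrays, whose smallest possible p is 0.00216. In simulated data with independent genes a shift of 0.15 of the circadian list, larger than the observed 0.07, was called and 0 other lists were. Independent genes cannot show false calls that arise from correlation between genes, so this result sets no bound on them.

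The genes named were chosen by a rule fixed at the same time: the 12 genes higher and the 12 lower with the lowest p, the 10 genes of the deposited table with the lowest p, up to 4 members of each list past the threshold, up to 4 members past an adjusted p of 0.05 over their list alone, and a fixed set of plasticity, transmitter and stress genes. Genes named outside the rule are said to be so in the part that names them.

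Alternatives fixed before the data were examined were a replicate block, a second quantile normalization, centring of arrays on their medians, the variance trend with and without robust fitting, array weights, covariates for RNA integrity, for oligodendrocyte markers and for striatal and central amygdala markers, each array left out in turn, other list tests, and a two-sample test. Alternatives chosen after seeing the data were a spike-in covariate, selection of probe sets anew under covariates, leaving out sucrose arrays 1, 2 and 5, and leaving out control arrays 3 and 5. Filters on dim probe sets had been planned and could not be run on ratios.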

Results

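The study asked which transcripts of the BLA differ in rats with a history of brief sucrose snacks from rats given water on the same schedule. The data are 12 arrays, 6 per group, each from a pool of 2 rats, with every value a ratio to the mean of the control arrays. Differences below are on the log2 scale, sucrose minus control, with the standard error of the limma fit, and n = 6 pools per group throughout. Values per group are given as mean ± SD of log2 ratios.

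Differences between the groups were small, and at the level of single probe sets none passed the test. Among the genes with the lowest p, Ank2, which encodes the neuronal scaffold ankyrin-B, was 0.35 ± 0.06 (SE) higher in sucrose arrays (0.35 ± 0.12 against 0.00 ± 0.10, SD), a 1.27-fold ratio. Phip was higher by 0.54 ± 0.10, the adhesion protein gene Adam23 by 0.36 ± 0.07, the extracellular matrix proteoglycan gene Vcan by 0.31 ± 0.06 and the exoribonuclease gene Xrn1 by 0.24 ± 0.04. In the other direction, the RNA helicase gene Dhx9 differed by -0.43 ± 0.07, a ratio of 0.741, and the angiogenic factor gene Vegfa by -0.17 ± 0.03. For Ank2, Adam23, Vcan, Xrn1, Dhx9 and Vegfa each of the 6 sucrose arrays lay beyond all 6 control arrays, while the ranges of Phip overlapped. All of these genes had an adjusted p of 0.231 in limma, so they are reported as differences that failed the correction.

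The remaining genes of lowest p showed the same scale of difference. On the higher side Rnf149, Cggbp1, Cbl (a ubiquitin ligase), Pi4k2b, Scd2 (a fatty acid desaturase), Appbp2 and Srrm1 (a splicing factor) differed by 0.35, 0.30, 0.21, 0.21, 0.17, 0.27 and 0.32, with an adjusted p of 0.231 for each. On the lower side Egfl7, an endothelial secreted factor, Mtarc1, Smad9, Cyp2s1, Ero1b, RGD1311745, Zfp787, Gfi1, Sapcd2 and Ttk lay between -0.33 for Ttk and -0.14 for Egfl7 and Ero1b, with an adjusted p of 0.376 for each. Not every probe set of the genes in this and the preceding paragraph went the same way. It was 1 of 2 for Vegfa, Rnf149, Smad9, Gfi1 and RGD1311745. For Scd2 2 of 4 did, for Xrn1 and Srrm1 2 of 3, for Vcan 3 of 5 and for Appbp2 3 of 4. The remaining genes, such as Ank2 with 3 of 3, had no probe set in the other direction.

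Over the 31042 probe sets limma called 0 at an adjusted p of 0.05 and 0 at 0.1, the lowest adjusted p being 0.231. At an unadjusted p under 0.05 there were 2351, of which 1398 were higher and 953 lower after sucrose, where 1552 are expected by chance from independent probe sets. Complete separation of the groups occurred for 132 probe sets, against 67 expected at the chance share of 0.216%. Correlation between probe sets widens the spread of such counts, and separation was not counted in other divisions of the arrays. Whether 132 exceeds chance was therefore not tested. Differences above 0.5 in size occurred for 18 probe sets. Without sucrose array 5, Phip passed (0.63, adjusted p = 0.0405), and without sucrose array 3 an unnamed probe set did (-0.29, adjusted p = 0.0228).

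At its preset correlation camera called 5 of 29 lists, all upward. In 99 other divisions of the same 12 arrays into 6 and 6 it called 1 to 12 lists, with a median of 6, so this number does not exceed chance. Calcium, cAMP and kinase signalling genes were shifted upward relative to other genes by camera at its preset correlation (adjusted p = 0.00578), a call lost with an estimated correlation (adjusted p = 0.555). Of 34 measured members 21 were higher and 13 lower, 10 were higher at an unadjusted p under 0.05 and 0 lower, and 0 passed over all probe sets. Adjusted over the list alone, 6 passed, among them Camk4 (0.24 ± 0.05, adjusted p = 0.0173), a nuclear calcium-dependent kinase, the coactivator gene Crebbp (0.38 ± 0.10, adjusted p = 0.0248), Prkce (0.23 ± 0.06) and Camk2a (0.36 ± 0.10), both with an adjusted p of 0.0257. Camk2a encodes the alpha subunit of the postsynaptic calcium/calmodulin kinase. All 4 of its probe sets were higher, 1 of them at an unadjusted p under 0.05. For Camk4 1 of 2 probe sets was higher, for Crebbp 4 of 5 and for Prkce 1 of 1. The list mean was 0.06 ± 0.01 in sucrose and 0.00 ± 0.05 in control arrays, with every sucrose array above every control array. The margin was narrow, with 0.047 in sucrose array 6 and 0.0456 in control array 4. Control arrays 1 and 5 were lowest, at -0.0784 and -0.0475. The exact permutation test of the list mean gave p = 0.00216, the smallest it can give, and an adjusted p of 0.0628. Over 29 lists a single list at this smallest p could not pass 0.05 unless other lists had a similarly low p. Without control array 1 the camera value was 0.0551.

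Circadian clock genes were also shifted upward by camera (adjusted p = 0.0113; adjusted p = 0.469 with an estimated correlation). Of 18 measured members 13 were higher and 5 lower, 3 were higher at an unadjusted p under 0.05, and 0 passed over all probe sets or adjusted over the list alone. The members with the lowest p were the clock output factor gene Tef (0.30 ± 0.08), the nuclear receptor genes Rorb (0.29 ± 0.11), Nr1d2 (0.22 ± 0.09) and Rora (0.14 ± 0.07). For Tef 3 of 3 probe sets were higher, for Rorb 2 of 2, for Nr1d2 3 of 3 and for Rora 1 of 2. The list mean was 0.07 ± 0.02 in sucrose and -0.01 ± 0.04 in control arrays, with an exact permutation p of 0.00649 and an adjusted p of 0.0942. All rats were killed in the morning, and the order of dissection is not given in the labels.

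**Figure D1:**
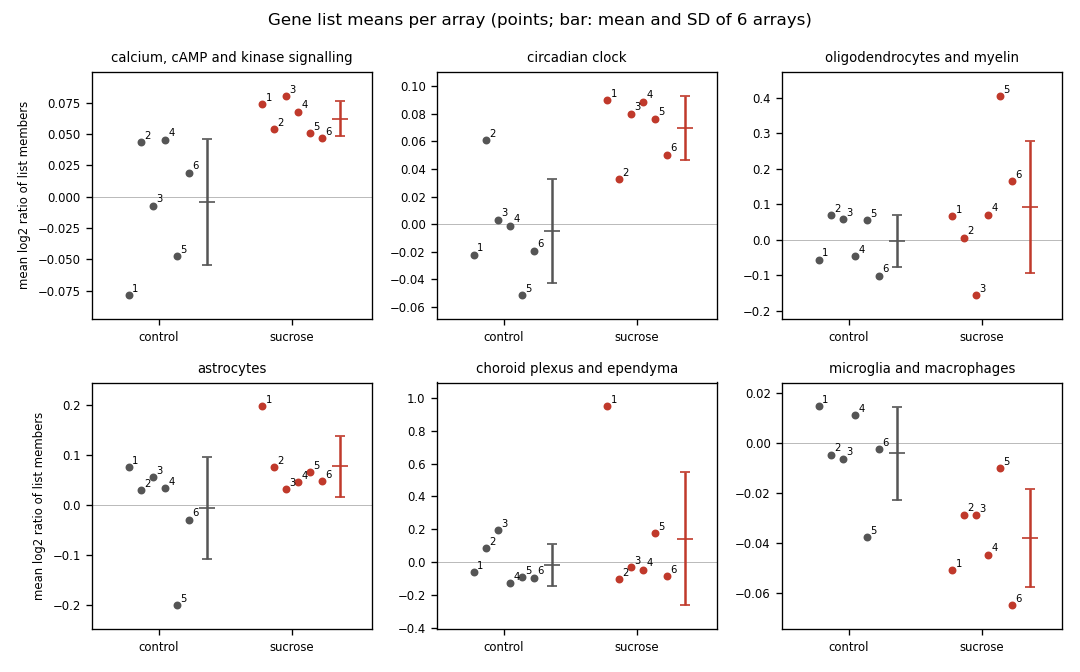
Mean log2 ratio of the members of 6 gene lists on each array, with the array number beside each point, control arrays on the left and sucrose arrays on the right of each panel, and a bar for the mean and SD of 6 arrays. Kinase signalling means of all sucrose arrays lay above those of all control arrays, the lowest at 0.047 against a highest control of 0.0456. The choroid plexus mean was 0.95 in sucrose array 1 and at most 0.18 in the other sucrose arrays.

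Markers of 3 non-neuronal tissues were shifted upward by camera, each with a large contribution of single arrays. Oligodendrocyte and myelin genes were higher in 18 of 19 members, with an adjusted p of 0.0013 and of 0.635 with an estimated correlation. Examples are Fa2h (0.25 ± 0.08), which makes myelin lipids, and Ermn (0.21 ± 0.10). The list mean was 0.41 in sucrose array 5 and -0.16 in sucrose array 3, and the adjusted p without array 5 was 0.143. Astrocyte genes were higher in 15 of 19 members, with an adjusted p of 0.0113 and of 0.635 with an estimated correlation; they included the glutamate transporter gene Slc1a2 (0.26 ± 0.10), Slc4a4 (0.35 ± 0.12), Id4 (0.21 ± 0.09) and the water channel gene Aqp4 (0.27 ± 0.12). Their adjusted p was 0.0667 without sucrose array 1 and 0.314 without control array 5. For Slc1a2 2 of 2 probe sets were higher, for Slc4a4 1 of 2, for Id4 2 of 4 and for Aqp4 2 of 3. Choroid plexus and ependyma genes were higher in 14 of 15 members, with an adjusted p of 0.0262 and of 0.652 with an estimated correlation. Among them were Kl (0.37 ± 0.33) and Folr1 (0.26 ± 0.19), and without sucrose array 1 the direction turned and the adjusted p was 0.95. No member of these 3 lists passed over all probe sets or adjusted over the list alone.

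The other 24 lists did not pass the test. Glutamatergic postsynapse genes had 9 members higher at an unadjusted p under 0.05 and 0 lower, and 0 of 34 passed over all probe sets or adjusted over the list alone (camera adjusted p = 0.0696), with a median of -0.01 and a mean of 0.05 that differ in sign. Gria1, an AMPA receptor subunit gene, differed by 0.18 ± 0.08, Grin1 by -0.09 ± 0.10 and Grin2b by 0.11 ± 0.06. Single members passed adjusted over the list alone in 5 further lists, namely Gabrb2 (0.32 ± 0.09) among 12 GABA receptor genes, Adra2c (0.35 ± 0.09) among 28 monoamine and acetylcholine receptor genes, Adipor2 (0.32 ± 0.08) among 23 feeding and metabolic hormone genes, Ank2 among 28 dendritic cytoskeleton genes and Vcan among 10 oligodendrocyte precursor genes. Camk2a and Neurod2 (0.19 ± 0.05) did so among 17 markers of pallial excitatory neurons. The camera adjusted p of these 6 lists was 0.0696, 0.653, 0.92, 0.0578, 0.0696 and 0.0696, in the order named. Adjustment over a list alone makes no correction across the 29 lists, so a passing member in some of them can arise by chance. For Gabrb2 1 of 2 probe sets was higher.

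Other neuronal lists gave a camera adjusted p of 0.165 for synaptic vesicle genes, 0.347 for neurotrophins, 0.927 for GABAergic neurons, 0.0696 for the opioid and endocannabinoid system, 0.0785 for voltage-gated ion channels, 0.153 for striatal and central amygdala markers and 0.927 for thalamic and hypothalamic markers. Stress peptides and corticosteroid receptors gave 0.915 and glucocorticoid-induced genes 0.0785. The metabolic and housekeeping lists gave 0.653 for oxidative phosphorylation, 0.192 for glycolysis, 0.239 for ribosomal proteins and 0.567 for blood cells, and the heat shock list 0.312. Endothelium gave 0.165. The list mean, the median and the direction of the test differed in sign for GABAergic neurons, feeding and metabolic hormone genes, heat shock genes and thalamic and hypothalamic markers, all with means within 0.01 of 0. Microglia and macrophage genes had 4 members lower and 0 higher at an unadjusted p under 0.05, with an adjusted p of 0.153. Among single genes of these systems, Gad1 differed by 0.15 ± 0.05, Oprm1 by 0.07 ± 0.06, Crh by -0.15 ± 0.11, Syp by -0.03 ± 0.03 and the glucocorticoid receptor gene Nr3c1 by 0.23 ± 0.08, none with an adjusted p under 0.5. For Gad1 and for Nr3c1 1 of 2 probe sets was higher. The striatal and central amygdala mean was -0.209, -0.129 and -0.114 in sucrose arrays 1, 2 and 3. It was 0.0362, 0.0679 and 0.0632 in arrays 4, 5 and 6, and -0.079 to 0.0906 in controls. Pallial marker means were 0.128, 0.0951 and 0.0962 in sucrose arrays 1, 2 and 3, and -0.00935 to 0.00803 in arrays 4, 5 and 6. With the oligodendrocyte covariate camera called the striatal list downward (adjusted p = 0.00145). This pattern was seen afterwards and its cause was not tested.

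Immediate early genes, which neurons transcribe within minutes of strong activity, showed no difference past the threshold (camera adjusted p = 0.75), and this value rests on a single array. Fos differed by -0.17 ± 0.47, Fosb by -0.33 ± 0.36, Arc by -0.01 ± 0.23, Egr1 by 0.05 ± 0.09 and Bdnf by -0.08 ± 0.12. In control array 2 the list mean was 0.53, and it was the highest of the 12 arrays for 27 of the 37 measured members, with Fos at 1.93, Fosb at 1.65 and Arc at 1.11. The list mean was -0.10 ± 0.04 in sucrose arrays and -0.20 ± 0.05 in the other 5 control arrays, and without control array 2 camera placed the list higher after sucrose with an adjusted p of 7.1e-05. That array was singled out by these very genes, and leaving out the highest control raises the difference by construction, so this value is not a test of sucrose.

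The authors' deposited table lists 145 probe sets, of which 136 were higher and 9 lower after sucrose, although the series design speaks of 145 upregulated genes. In the authors' deposited table the ratios of the higher probe sets ran from 1.198 to 2.007 with a median of 1.241, and its p-values ran from 0.000225 to 0.05. The unadjusted test that gives back these p-values, at 0.05 and with a geometric ratio of at least 1.2, selected 150 probe sets here, 140 higher and 10 lower, and these included all 145. All 145 had an unadjusted limma p under 0.05 and 0 had an adjusted p under 0.05, the lowest being 0.231. Its named genes of lowest p were Dhx9, Rnf149, Ank2, Cggbp1, Vcan, Adam23, Phip, Appbp2, Srrm1 and the orphan receptor gene Gpr61 (0.32 ± 0.06). For Gpr61 1 of 2 probe sets was higher. The 93 genes named by higher probe sets included 2 circadian genes, Rorb and Tef, against 0.12 expected (one-sided Fisher exact p = 0.00605, adjusted p = 0.175 over 29 lists), and equally 2 kinase signalling genes, Camk2a and Crebbp, and 2 glutamatergic postsynapse genes, Gria3 and Grin2a, each pair against 0.22 expected (adjusted p = 0.2 for both lists). The other lists had 0 or 1 such gene, and Gria3 and Grin2a, outside the rule for named genes, were named after their values were seen. The table was chosen on these same arrays, so it is not independent evidence of the direction of any list. With the spike-in level as a covariate the same limits selected 75 probe sets, 66 higher and 9 lower, while the mean difference of the 136 higher probe sets was 0.28 against 0.33. Of its 145 probe sets, already selected on all 12 arrays, 107 had an unadjusted p under 0.05 without control arrays 3 and 5, and 116 without sucrose arrays 1, 2 and 5.

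**Figure D2:**
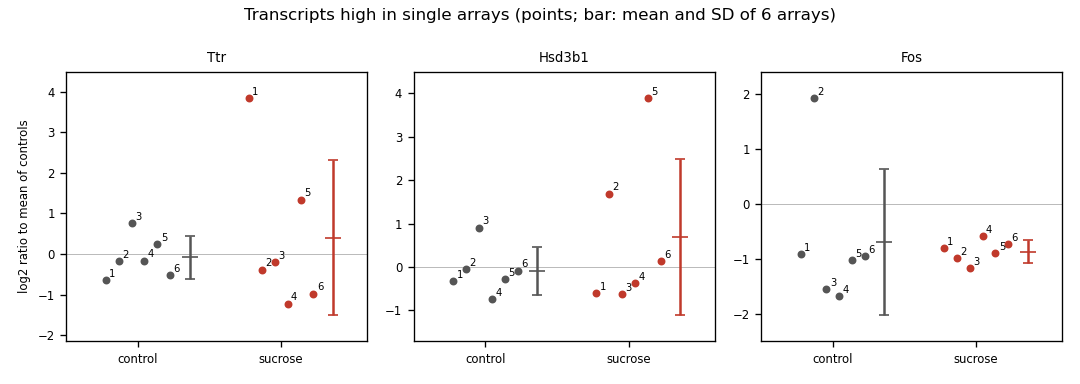
Log2 ratio of Ttr, Hsd3b1 and Fos on each array, with the array number beside each point, control arrays on the left and sucrose arrays on the right of each panel, and a bar for the mean and SD of 6 arrays. Ttr was 3.84 in sucrose array 1, Hsd3b1 3.89 in sucrose array 5 and Fos 1.93 in control array 2, each far from the rest of its group.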

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

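The tests of choroid plexus and adrenal cortex genes and of sucrose in single arrays were chosen after the result was seen. The counts over other splits, the repeated selections and the testis test were written before their results, but Cyp17a1, 1 of the 11 testis genes, had been looked at, and the repeated selections replaced tests on the already chosen probe sets whose results had been seen (differences of 0.27 without control arrays 3 and 5, 0.28 with the spike-in level and 0.32 with RNA integrity as a covariate). Genes of choroid plexus, adrenal and testis other than Kl and Folr1 lie outside the rule for named genes and were, apart from most testis genes, chosen after their values were seen. A value was singled out where an array lay far from the other 5 of its group, by Dixon's criterion at the 95% level. Of 190 groups of 6 values examined 21 met it, where chance gives about 10.

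The counts across all genes were set against other ways to divide the 12 arrays into 6 and 6, of which 100 of 462 were drawn with the real one included. An adjusted p under 0.05 was reached by 0 probe sets in the real split and by up to 58 in others, so that all 100 had as many. The 2351 probe sets at an unadjusted p under 0.05 were matched or exceeded in 11 splits, with 4162 as the highest other. The 5 lists were matched or exceeded in 69 splits. The other splits called 1 to 12 lists, with a median of 6. The number of lists called at the preset correlation was therefore no larger than other splits typically gave, and chance cannot be excluded for it. The 150 probe sets chosen by the rule of the deposited table were matched or exceeded in 5 splits, 317 being the highest other, which is at the limit set beforehand and does not exclude chance. Of the 99 other splits 5 had any call, with 1, 1, 1, 5 and 58 probe sets, and whether this exceeds chance was not tested.

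The 136 probe sets of the deposited table that were higher after sucrose had a mean of 0.52 in sucrose array 1 and from 0.20 to 0.33 in the other sucrose arrays, against -0.17 to 0.17 in controls, a difference of 0.33 that is inflated because they were chosen for it. Within groups this mean followed the spike-in level, with a slope of 0.99 (95% interval 0.31 to 1.67), but the spike-in level differed between groups by only 0.05 (exact permutation p = 0.361), which at the upper end of this interval gives 0.08 of the 0.33. Sucrose array 1 had the highest spike-in level of the 12 arrays (0.183) and the lowest 3-prime minus 5-prime difference (-0.137). It also had the lowest value on the second principal component (-19.5). Selections with a covariate used the ordinary t-test of a linear model and not the Welch test, in all splits alike. When probe sets were selected anew by the same limits with the spike-in level as a covariate, 75 were found, 66 of them higher, and 24 of 100 splits gave as many (highest other 295). Differences in hybridisation thus remain a candidate explanation, of a small part by the slope and of an unknown part of the count. With the RNA integrity measure 137 were found and 4 of 100 splits gave as many (highest other 173), just under the limit of 5 set beforehand. This argues against RNA integrity as the whole cause only if the count exceeds chance. The 5 of 100 splits found without a covariate do not establish that. Without control arrays 3 and 5, which stand apart on the first principal component, 62 were selected, 47 higher and 15 lower after sucrose, and 16 of 100 splits of these 10 arrays gave as many in both directions together, with 228 as the highest other. A contribution of these 2 controls, chance and an effect of sucrose cannot be told apart with 10 arrays.

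Choroid plexus and ependyma genes had a mean of 0.95 in sucrose array 1, with Ttr at 3.84, Kl at 1.72, Folr1 at 1.29, F5 at 1.21 and Cldn2 at 1.06. Tissue of the choroid plexus, which lies in the ventricle next to the amygdala, is a candidate source, since 13 of the 15 genes were highest in this array, where chance gives 1.2. The other 5 sucrose arrays did not share the rise, and their mean differed from the controls by -0.0014 (exact permutation p = 0.994). Array 1 was left out because these genes were high there, which lowers the sucrose mean by construction. The value therefore speaks only against a rise shared by all sucrose pools. The genes were known to be high in array 1 before the test was written, so the source remains a hypothesis.

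Steroid synthesis genes were high in sucrose array 5 and less so in array 2, with Hsd3b1 at 3.89 and 1.69, Cyp11a1 at 3.26 and 1.47, Akr1b7 at 3.18 and 1.63, and Star at 1.65 and 0.15. RNA of adrenal cortex carried into these pools is a candidate source that the data leave open: these 4 genes prompted the question, and of the 8 other cortex markers 2 were highest in array 5, Cyp11b1 (1.10) and Cyp21a1 (0.74), both already seen. The other 6, such as Nr5a1 (-0.10), Scarb1 (0.04) and Fdx1 (0.06), were not, and brain also expresses the last pair. Testis is argued against by a median of -0.0592 over 11 testis genes, and 8 markers of adrenal medulla had a median of -0.02. In the other 4 sucrose arrays Cyp11a1, Hsd3b1 and Akr1b7 had a mean of -0.36, against 3.44 in array 5 and -0.06 in controls. Arrays 5 and 2 were left out because these genes were high there, which lowers this mean by construction. It therefore speaks only against a rise shared by all sucrose pools.

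Other values far from their group are given without explanation. In control array 2 the immediate early list mean was 0.53, Fos was 1.93, Fosb 1.65, Arc 1.11 and Egr1 0.50. In control array 1 the list means were -0.0668 for stress peptides and corticosteroid receptors and -0.0893 for voltage-gated ion channels, and Rorb was 0.38. In sucrose array 6 the list means were -0.0423 for oxidative phosphorylation, -0.0411 for ribosomal proteins and -0.0196 for heat shock genes, Pi4k2b was 0.325 and Ero1b was -0.23. In sucrose array 1 the list means were 0.0694 for thalamic and hypothalamic neurons and 0.20 for astrocytes, and Cggbp1 was 0.52, Vcan 0.42, Folr1 1.29 and Gria1 0.48. Syp was 0.0892 in control array 3.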

How the results depend on the processing

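Planned filters on dim probe sets were not run, because ratios keep no signal level. The cause of the changes below was not tested. The number of probe sets past an adjusted p of 0.05 was 0 in limma under nearly all settings, also by the two-sample test, and 1 with the oligodendrocyte covariate (Phip); leaving out single arrays gave 0 to 1. At an unadjusted p under 0.05 it was 1543 without sucrose arrays 1, 2 and 5 (chosen after seeing the data), and with all 12 arrays 1681 with a second quantile normalization, 1670 with trend and robust fitting and 1818 with the spike-in covariate, against 2351 and 1552 expected by chance; it was 1923 to 2751 with single arrays left out. With the replicate block 2252 were found and the calls stayed at 0. Residuals of equally numbered arrays correlated from -0.15 to 0.19, and 1 of 6 sucrose arrays correlated best with its own number, so the numbers were not read as pairs. Of the 145 deposited probe sets 142 to 145 stayed under an unadjusted p of 0.05 with single arrays left out. They had been selected at this limit on the same 12 arrays, so this was largely fixed in advance and is not a test of them.

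The number of lists called was 5, and it was 3 with array weights, 9 with the oligodendrocyte covariate, 3 with the spike-in covariate, 8 without control arrays 3 and 5, 0 with an estimated correlation, 0 with fry, and 3 to 12 with single arrays left out; the highest, 12, was without sucrose array 5. The choroid plexus list had an adjusted p of 0.0856 with a second quantile normalization, 0.0617 with array weights, 0.0987 with the RNA integrity covariate, 0.0858 with the oligodendrocyte covariate, 0.0724 with the striatal covariate, 0.208 with the spike-in covariate, and 0.761 in the opposite direction without sucrose arrays 1, 2 and 5. The astrocyte list had 0.0617 with array weights, 0.116 with the spike-in covariate, 0.32 without sucrose arrays 1, 2 and 5, and 0.192 without control arrays 3 and 5. The oligodendrocyte list had 0.289 without sucrose arrays 1, 2 and 5. With an estimated correlation the values were 0.555 (kinase signalling), 0.469 (circadian), 0.635 (oligodendrocytes), 0.635 (astrocytes) and 0.652 (choroid plexus), and with fry, which tests lists against no change and not against other genes, 0.367, 0.367, 0.66, 0.66 and 0.677. With single arrays left out the ranges were 0.00231 to 0.0551 for kinase signalling, 0.00255 to 0.0371 for the circadian list, 2.86e-09 to 0.143 for oligodendrocytes, 0.000484 to 0.314 for astrocytes, and 0.00421 to 0.95 for choroid plexus, which turned direction without sucrose array 1. The immediate early list ran from 7.1e-05, in the opposite direction without control array 2, to 0.977. Of 1512 values of named probe sets 1510 kept their side of the threshold. No named probe set passed in the main fit, so this means only that they still did not pass. Of these values 9 changed sign, all of them of Fos, Fosb, Arc, Bdnf or Egr1.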

Other observations

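Several transcripts varied strongly between arrays of one group without following the treatment. After Ttr and Hsd3b1, the named genes with the largest residual SD on the log2 scale were Slc3a1 (1.18) and Ythdf2 (1.17), with Mis18a (1.07), Dguok (0.99), Nt5dc1 (0.92) and Chrna5 (0.65) further down; they were chosen after their values were seen. Immediate early genes of control array 2 belong to the same group of highly variable transcripts, with a residual SD of 0.95 for Fos and 0.77 for Egr2.

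Microglia and macrophage genes had a mean of -0.04 ± 0.02 in sucrose and 0.00 ± 0.02 in control arrays (SD, n = 6 each; exact permutation p = 0.0216, adjusted p = 0.173 over 29 lists). The members with the lowest p were the complement genes C1qb (-0.09 ± 0.04, SE) and C1qc (-0.11 ± 0.04), Ptprc (-0.13 ± 0.05) and Cd68 (-0.10 ± 0.04), none of which passed adjusted over the list alone (0.231 each). Of 24 measured members 14 were lower and 10 higher. Dendritic cytoskeleton genes had an exact permutation p of 0.0238 and an adjusted p of 0.173, with Ank3 at 0.18 ± 0.06 and Map2 at 0.26 ± 0.11. Members of this list went both ways, and Actn2 was lower (-0.10 ± 0.04). These genes were named after their values were seen.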
